A study of Homo sapiens with 12 samples.

How the data were processed

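Total RNA of 12 MV4-11 cultures in 4 groups of 3 was sequenced after removal of ribosomal RNA with a stranded total RNA kit, per the labels' protocols. The groups crossed a guide (gNT or gRNF4) with a treatment (DMSO or GSK3685032 at 100 nM for 7 days). Group membership was taken from the sample titles and descriptions. The genotype field of the labels follows the treatment and not the guide, and was not used. The labels give the cell type as macrophage, whereas MV4-11 is an established leukaemia line. Per the submitters' processing notes, STAR 2.5.3a and featureCounts were used with the builds hg38 and GRCh38.p13. The deposited values of both tables are whole read counts, with 1 table for genes and 1 for numbered intergenic features. The strand setting, the annotation release and the definition and positions of the intergenic features are not given in the sources used here. Reads of overlapping or antisense genes can therefore be mixed, and those of near-identical copies, among them MAGEA, SSX, HLA and histone genes, are uncertain. Editing of RNA, which needs reads, was not analysed here.

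The gene table held 60649 genes, 60507 of them with a symbol. Library totals ran from 5130857 to 7456860 gene counts and from 272675 to 405504 intergenic counts. Genes with too few counts by the filter of edgeR on the 4 groups were left out, and 15937 genes and 5123 intergenic features were tested. Of the tested genes 15912 had a symbol and 15709 had a position in GENCODE release 29, from which the GRCh38 coordinates were taken. CPM values were counts scaled to library sizes times TMM factors. For intergenic features the gene totals and gene factors were used.

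Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, in a single fit of the 4 group means with robust dispersion, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 5 comparisons were the compound in gNT, the compound in gRNF4, the RNF4 guide with DMSO, the RNF4 guide with the compound, and the difference of the compound's effect between guides. The standard error of a log2 fold change was its size divided by the square root of the F statistic. A fold against a group at 0 was computed against a floor of 3 counts over the group, and genes with 1 to 3 counts in a group are given as CPM. Floors and binomial intervals (exact Clopper-Pearson, 95%) cover counting error only. The step was tested on simulated data for the compound in gNT with 15937 genes: edgeR recovered 31.3% of 67 genes changed by 1.5-fold, 65.7% of 67 changed by 2-fold and 90.9% of 66 changed by 4-fold, and 9 of 134 calls were false.

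The 25 gene lists were written before the data were examined, from general knowledge, as were the comparisons, the rule for named genes and all alternatives but 2. Lists were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset correlation of 0.01 and with an estimated correlation, adjusted over 125 tests. The lists covered germline genes, interferon-stimulated genes, interferon ligands and sensors, MHC class I and II, DNA methylation, the SUMO pathway, p53 targets, DNA repair, S phase, G2/M, monocyte, granulocyte, stem and KMT2A, erythroid and lymphoid markers, imprinted genes, retroelement genes, RNA editing, NF-kB and cytokines, apoptosis, the stress response, cholesterol synthesis, ZNF symbols and replication-dependent histones. Named genes were RNF4 and DNMT1, for each comparison up to 6 genes with the largest increase and 6 with the largest decrease among called genes with an average log2 CPM of at least 1 and no overlap between the groups' libraries, and up to 4 members of each list with the smallest p. XIST and genes of the Y chromosome were left out, and a few other genes that meet the rule are not reported here. Shares of counts were compared by exact permutation, two-sided, with 20 arrangements for a pair of groups, 400 within guides or treatments and 64 within pairs.

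Same-numbered libraries of both guides deviated together from their group means (correlations 0.62, 0.29 and 0.39 with DMSO, and 0.22, 0.27 and 0.22 with the compound). The replicate number was therefore read as pairing the libraries in the comparisons between guides. The blocked value is given beside those comparisons and the interaction where it changed the call of a list or the number of calls by over 1.5 times. Counts of list members, and SE and adjusted p of single genes, were taken without the block. Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, no filter or a stricter one, the block, the compared groups alone, an added fold threshold, and each library left out in turn. A fit without both DMSO libraries numbered 1 and the permutation within pairs were added after seeing the data.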

Results

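Total RNA was sequenced from MV4-11 cells, an established human line from an acute myeloid leukaemia that carries a KMT2A fusion. The cells carried a control guide named gNT or a guide named gRNF4. They were grown for 7 days with the vehicle DMSO or with GSK3685032 at 100 nM. GSK3685032 is a selective inhibitor of DNMT1, the methyltransferase that copies DNA methylation after replication, and RNF4 is a ubiquitin ligase that binds proteins carrying SUMO chains. The 12 libraries formed 4 groups of 3, and the question of the series was how reduced RNF4 alters the expression changes brought about by the compound. Gene counts summed to 6534915, 6483871 and 7360204 in the gNT libraries with DMSO, numbered 1 to 3, and to 5130857, 6413352 and 6228025 in the gNT libraries with the compound. The corresponding totals were 6357946, 7152408 and 7399803 for gRNF4 with DMSO and 6176270, 6300161 and 7456860 for gRNF4 with the compound. Of 60649 genes counted, 15937 had enough counts for testing. A principal component analysis placed treated and vehicle libraries apart on the first component, which held 52.3% of the variance. On the second component, with 13.7% of the variance, the DMSO libraries numbered 1 stood apart from the rest, at 39.2 for gNT and 35.7 for gRNF4, while the other 10 libraries lay between -30 and 11.7. Mitochondrial genes held 1.35% ± 0.39 (SD, n = 3) of gene counts in gNT with DMSO and 2.15% ± 0.093 in gNT with the compound. In gRNF4 the mitochondrial share was 1.55% ± 0.15 with DMSO and 1.51% ± 0.29 with the compound.

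RNF4 (ENSG00000063978.16, chromosome 4, 2462220 to 2625320 in GRCh38) was measured at 107 ± 3.3 CPM (counts scaled to library size, mean ± SD, n = 3) in gNT with DMSO and at 92.9 ± 9.9 CPM in gRNF4 with DMSO. With the compound its level was 120 ± 3.9 CPM in gNT and 88.1 ± 6.7 CPM in gRNF4. The single libraries with DMSO held 104.7, 106.4 and 111 CPM of RNF4 with gNT and 85.75, 88.74 and 104.2 CPM with gRNF4. Those with the compound held 123.8, 121.4 and 116.1 CPM of RNF4 with gNT and 88.11, 81.34 and 94.72 CPM with gRNF4, so every gRNF4 library lay below every gNT library of its treatment. Under edgeR the log2 fold change of RNF4 between guides was -0.21 with DMSO (SE 0.09, adjusted p = 1) and -0.45 with the compound (SE 0.09, adjusted p = 0.00986). The latter adjusted p of RNF4 under edgeR was 0.0602 without treated gNT library 1 and 0.0576 without treated gRNF4 library 2. The position of the guide in RNF4 is not given in the sources used here, and a transcript can persist when a guide disrupts its reading frame, so these levels do not measure the loss of RNF4 protein. DNMT1 (ENSG00000130816.17, chromosome 19, 10133345 to 10231286), the target of the compound, was at 803 ± 94 CPM in gNT with DMSO and 614 ± 52 CPM with the compound, and at 784 ± 87 and 685 ± 51 CPM in gRNF4.

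**Figure D1:**
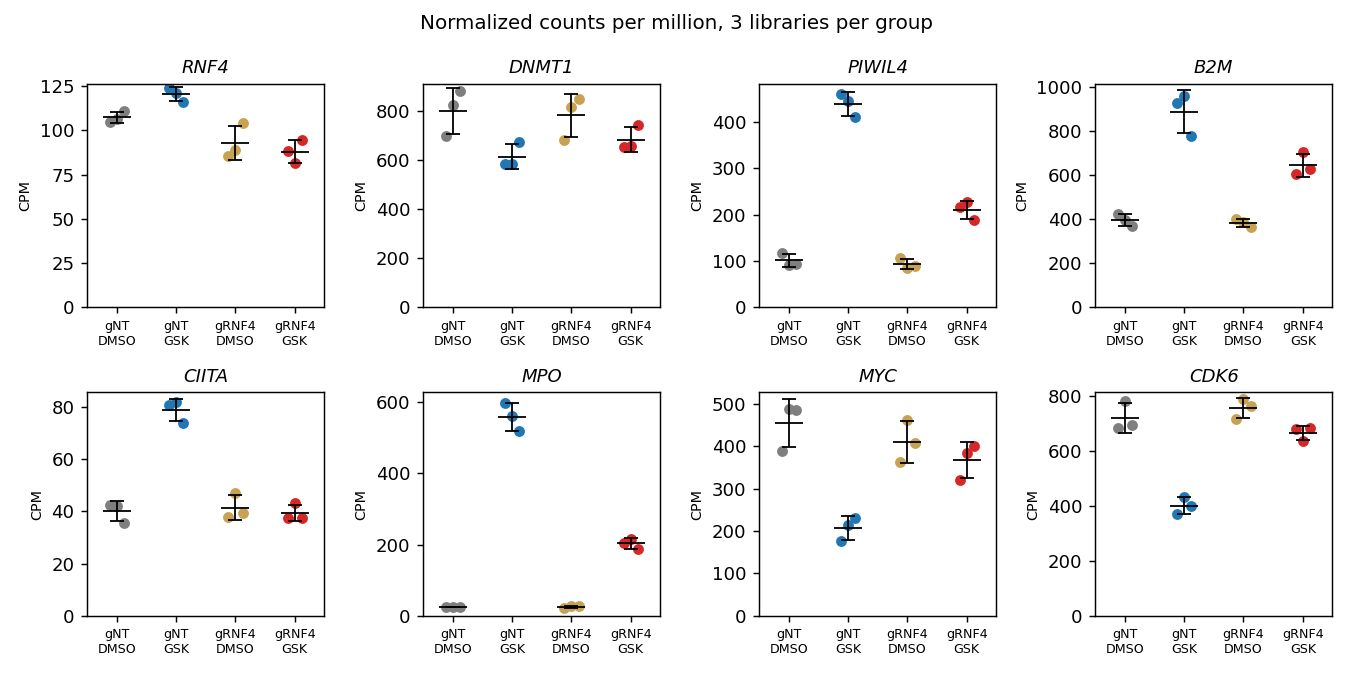
Normalized CPM (y axis, linear, from 0) of 8 genes in the 4 groups; each point is 1 of 3 libraries, the long bar is the mean and the whiskers are 1 SD. MPO rose from 24.6 to 559 CPM with the compound in gNT and from 25.1 to 203 CPM in gRNF4, while CIITA was at 39.5 CPM in treated gRNF4 and 78.9 CPM in treated gNT.

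The first comparison asked what the compound did to cells with the control guide. Genes of the germ line and of cancer-testis families, which adult somatic cells keep silent, rose together. Of 37 tested members of that list, 26 were higher and 1 was lower, and the same numbers held when adjusted over the list alone. That list held 107 genes, and the count filter chose the 37. Of these, 12 had 0 counts in gNT with DMSO and could pass the filter only through other libraries. Shares and set tests of lists silent with DMSO can be raised by this choice. It also bears on retroelement genes (10 tested of 31) and lymphoid markers (13 of 49). PIWIL4, which binds small RNAs that silence transposons, rose from 101 ± 13 to 439 ± 25 CPM (n = 3), and its relative PIWIL2 rose from 0.352 ± 0.35 to 24.3 ± 3.5 CPM. TDRD12, a partner of the same pathway, rose by 4.55 ± 0.35 (log2 fold change ± SE), and TDRD9 went from 0.0934 ± 0.16 to 44.5 ± 14 CPM. The single lower member was HORMAD1, at -0.30, which was named after its value was seen; with treated gNT library 1 left out, 0 members were lower. Antigen presentation rose as well. Of 18 tested genes of the MHC class I route, 11 were higher and 0 lower, and the same adjusted over the list alone. Among them were the coactivator NLRC5 (1.55 ± 0.10), HLA-B (1.32 ± 0.12), the peptide transporter TAP1 (1.73 ± 0.18) and B2M, which went from 397 ± 27 to 890 ± 96 CPM. Of 16 class II genes, 10 were higher and 0 lower, or 11 and 0 adjusted over the list alone. They were led by the class II transactivator CIITA (0.98 ± 0.11), HLA-DQB1 (1.35 ± 0.17), HLA-DPA1 (2.83 ± 0.34) and HLA-DPB1 (3.54 ± 0.46).

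Over all 15937 genes, edgeR called 2228 higher and 1940 lower in gNT at a false discovery rate of 0.05. Of these, 1018 and 357 changed by more than 1 on the log2 scale. The balance depended on the scaling. Upper-quartile factors gave 2425 higher and 1701 lower, library sizes alone 2526 and 1540, and the size factors of DESeq2 2165 and 2031. Some genes without a single read in the gNT libraries with DMSO rose. MYO18B was at least 131-fold higher, PNMA6E at least 122-fold, the neuronal receptor SLITRK5 at least 89.7-fold and MAEL, a piRNA pathway gene, at least 64.7-fold, each set against a floor of 3 counts over the group. MAGEA2 was at least 54.4-fold higher, though its reads cannot be told from those of the near-identical MAGEA2B. In all, 45 called genes had 0 counts in gNT with DMSO and 5 had 0 counts in gNT with the compound. Among the decreases, the chemokine CCL4 went from 9.08 ± 10 to 0.104 ± 0.18 CPM, XIRP1 was at least 19.7-fold lower and IGLL1, the surrogate light chain of early B cells, fell by 5.15 (SE 0.95) on the log2 scale. Each of these 3 genes was highest in gNT DMSO library 3, where CCL4 stood at 20.58 CPM against 3.935 and 2.719 CPM in libraries 1 and 2. DNMT1 fell by 0.39 (SE 0.11, edgeR adjusted p = 0.0198), and its adjusted p was 0.0512 without gNT DMSO library 2, 0.0747 without gNT DMSO library 3, 0.0867 without treated gNT library 1 and 0.0776 without treated gNT library 2.

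Cell cycle genes fell in gNT. Of 50 tested S-phase genes 28 were lower and 0 higher, and 32 were lower when adjusted over the list alone. Examples were PRIM1, the small subunit of primase (-1.01 ± 0.13), RRM2, a subunit of ribonucleotide reductase (-0.87 ± 0.12), and RFC4 (-0.90 ± 0.15). Of 56 G2/M genes 37 were lower and 0 higher, or 41 lower adjusted over the list alone. TPX2 was at -0.72 ± 0.11 and KIF2C at -0.79 ± 0.13. Replication-dependent histone genes had 46 lower and 4 higher of 60 tested, or 49 and 4 adjusted over the list alone. H2AC20 changed by -1.10 ± 0.13 and H2BC17 by -1.35 ± 0.16, whereas H1-1 (5.61 ± 0.44) and H3C6 (2.80 ± 0.19) rose. DNA repair genes had 16 lower and 1 higher of 52, or 18 and 1 adjusted over the list alone. Among them MRE11 was at -1.19 ± 0.11 and BRCA2 at -0.83 ± 0.13. Genes of the stress response and of amino acid supply had 17 lower and 3 higher of 42, or 21 and 3 adjusted over the list alone, and their median log2 fold change was -0.64. Among them the amino acid carriers SLC7A5 (-2.00 ± 0.23), SLC7A1 (-1.41 ± 0.15) and SLC3A2 (-1.42 ± 0.16) and the serine enzyme SHMT2 (-1.48 ± 0.18) fell. NF-kB targets and cytokines had 13 lower and 2 higher of 28, or 17 and 4 adjusted over the list alone. Among them were TNFAIP3 (-1.79 ± 0.22), NFKB2 (-1.17 ± 0.17) and IL1RN (-1.50 ± 0.24). Without both DMSO libraries numbered 1, which stood apart on the second component, the lower members numbered 46 for S phase, 38 for G2/M, 50 for histones, 32 for repair, 16 for the stress response and 14 for NF-kB, a recount chosen after seeing the data.

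Genes of the myeloid lineage moved both ways in gNT. Of 16 tested granulocyte genes 5 were higher and 2 lower, or 5 and 3 adjusted over the list alone. MPO, the peroxidase of primary granules, rose from 24.6 ± 0.8 to 559 ± 40 CPM, ELANE by 1.16 ± 0.16 and CSF3R by 0.99 ± 0.13, while CXCR2 fell by 1.39 (SE 0.18). Monocyte and macrophage markers had 11 higher and 6 lower of 38, or 12 and 6 adjusted over the list alone. CD36 was at 2.36 ± 0.24, MNDA at 2.37 ± 0.24 and AIF1 at -1.50 ± 0.15. Stem-cell genes and targets of KMT2A fusions had 13 lower and 3 higher of 27, or 14 and 4 adjusted over the list alone. MYC went from 454 ± 57 to 208 ± 28 CPM and CDK6 from 720 ± 54 to 401 ± 30 CPM, while HOXA13 rose by 2.30 ± 0.24 and ADCY9 by 0.92 ± 0.09. Erythroid and megakaryocyte markers had 5 higher and 2 lower of 13, the same adjusted over the list alone, with NFE2 at 1.37 ± 0.15 and KLF1 at 3.66 ± 0.62. Lymphoid markers had 4 higher and 3 lower of 13, the same adjusted over the list alone. The B-cell kinase BLK went from 0.104 ± 0.09 to 11.6 ± 1.6 CPM and NCAM1 changed by -1.60 ± 0.25. Of 34 imprinted genes 10 were higher and 3 lower, or 14 and 5 adjusted over the list alone. SNHG14 was at 1.33 ± 0.14, SNRPN at 1.17 ± 0.21 and CRYBG1 at 1.03 ± 0.09. Genes derived from retroviruses and other retroelements had 4 higher and 0 lower of 10, or 5 and 0 adjusted over the list alone. PNMA5 rose from 0.354 ± 0.11 to 101 ± 5.8 CPM. Of 369 genes with a ZNF symbol, a family that holds most KRAB repressors, 68 were higher and 23 lower, the same adjusted over the list alone. ZNF595 was at 3.77 ± 0.31 and ZNF772 at 2.59 ± 0.28.

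Interferon-stimulated genes had 15 higher and 6 lower of 76 in gNT, the same adjusted over the list alone. IFITM3 (2.24 ± 0.21), IFI27 (3.65 ± 0.37) and TDRD7 (1.22 ± 0.15) were among those that rose. Their median was 0.26. Without gNT DMSO libraries 1, 2 and 3 in turn, 24, 10 and 11 were higher, with medians of 0.62, 0.03 and 0.11. Without treated gNT libraries 1, 2 and 3 in turn, 12, 9 and 15 were higher, with medians of 0.19, 0.16 and 0.33. Without both DMSO libraries numbered 1, 39 were higher and 6 lower. Interferon ligands, receptors and sensors had 3 higher and 2 lower of 16, or 4 and 2 adjusted over the list alone, with a median of 0.14 and a mean of -0.02. MYD88 rose by 0.68 ± 0.11 and IFNAR2 by 0.86 ± 0.16. The DNA sensor AIM2 fell, at -3.13 in gNT (edgeR adjusted p = 0.00338) and -3.32 in gRNF4 (edgeR adjusted p = 0.00738). It kept both calls with any 1 library left out. Writers, readers and erasers of DNA methylation had 4 higher and 4 lower of 24, the same adjusted over the list alone. ZBTB4 was at 1.02 ± 0.10, TET3 at -0.41 ± 0.07 and UHRF2 at -0.53 ± 0.10. SUMO pathway genes had 8 lower and 2 higher of 37, the same adjusted over the list alone. UBA2, a subunit of the SUMO-activating enzyme, changed by -0.37 ± 0.08 and UBE2D1 by 0.76 ± 0.13. With library sizes alone as the scaling, 3 SUMO genes were lower and their median turned from -0.03 to 0.03. The lower SUMO genes numbered 1, 2 and 3 without treated gNT libraries 1, 2 and 3 in turn, and 8, 4 and 3 without gNT DMSO libraries 1, 2 and 3. Targets of p53 had 9 higher and 5 lower of 43, or 10 and 5 adjusted over the list alone, with DRAM1 at 1.41 ± 0.20 and CCNG1 at -0.71 ± 0.12. RNA-editing and deaminase genes had 5 lower and 1 higher of 20, or 6 and 1 adjusted over the list alone. ADARB1 was at -0.74 ± 0.14, APOBEC3C at -0.61 ± 0.09 and RBM47 at 1.98 ± 0.30. Apoptosis genes had 5 higher and 5 lower of 38, the same adjusted over the list alone. Over all 15937 genes 2228 were higher and 1940 lower in gNT. The apoptosis and DNA methylation counts lie near those shares and are not particular to these lists. BCL2L11, a killer of the BCL2 family, rose by 0.76 ± 0.10 and BCL2 fell by 0.60 (SE 0.11). Cholesterol synthesis genes had 2 higher and 0 lower of 24, the same adjusted over the list alone, with TM7SF2 at 1.26 ± 0.17.

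As sets against all other genes, 14 of the 25 lists passed the camera test in gNT after adjustment over 125 list tests, and 0 did with an estimated correlation between members. Higher sets were the germline list (adjusted p = 5.78e-16, and adjusted p = 0.0754 with an estimated correlation), MHC class I (9.28e-07, and p = 0.352 with an estimated correlation) and class II (5.92e-05, and p = 0.507 with an estimated correlation). Imprinted genes (0.0197), retroelement genes (0.0223) and ZNF genes (0.0325) also ranked higher, and their adjusted p with an estimated correlation was 0.538, 0.507 and 0.538. Lower sets were histones (adjusted p = 1.36e-17), G2/M (2.08e-13), S phase (6.74e-11), repair (1.63e-06), the stress response (0.000344), NF-kB (0.00118), the stem and KMT2A list (0.00283) and RNA editing (0.0355). For those lower sets the adjusted p with an estimated correlation was 0.507, 0.538, 0.568, 0.538, 0.538, 0.568, 0.352 and 0.474 in the same order. RNA editing lost its camera call without gNT DMSO library 3 (adjusted p = 0.0781). ZNF genes lost theirs without gNT DMSO library 2 (camera adjusted p = 0.0782), gNT DMSO library 3 (0.0718) or treated gNT library 2 (0.0517). Without treated gNT library 1, edgeR called 2538 genes in all, and the lower members numbered 10 for S phase, 17 for G2/M and 10 for repair, while the higher germline members still numbered 26.

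**Figure D2:**
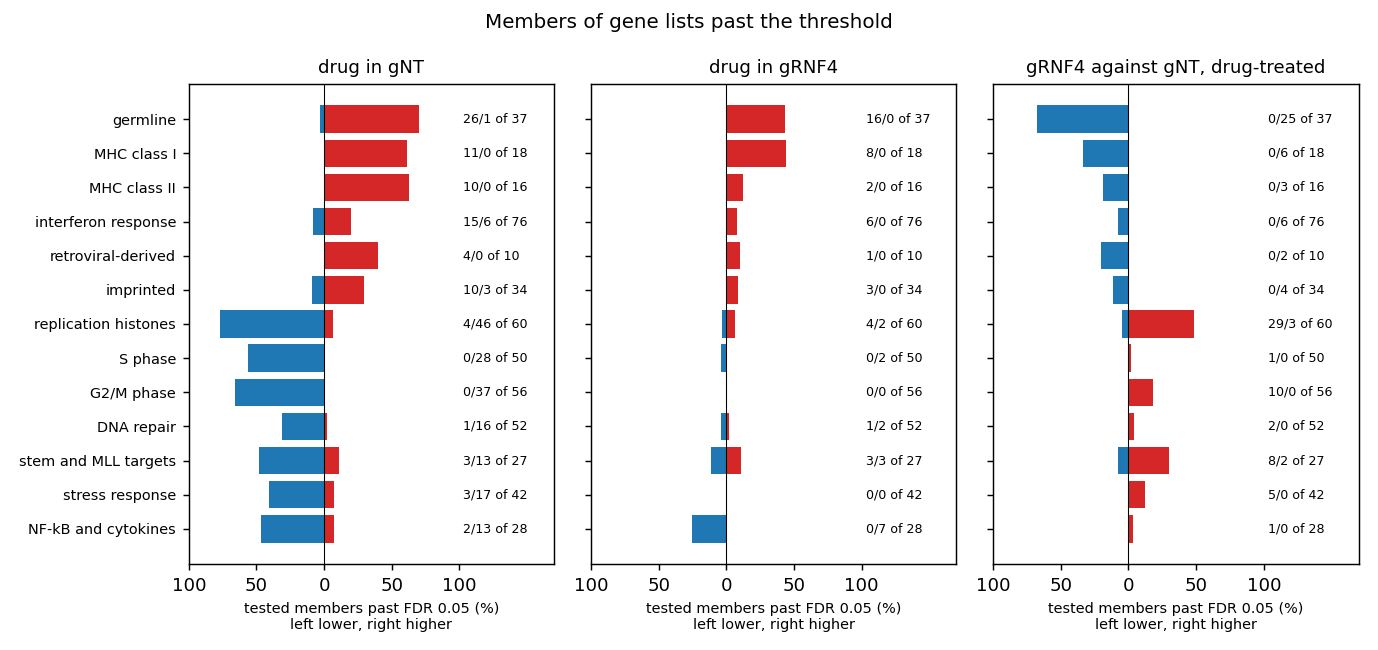
Share of tested members of 13 gene lists (x axis, percent) that were higher, to the right in red, or lower, to the left in blue, at an edgeR false discovery rate of 0.05, for the compound in gNT, the compound in gRNF4, and gRNF4 against gNT among treated libraries; the numbers at the right give higher, lower and tested members. Of 37 germline genes, 26 were higher with the compound in gNT, 16 in gRNF4, and 25 were lower in treated gRNF4 than in treated gNT.

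The second comparison gave the response to the compound in cells with the RNF4 guide. Germline genes rose here too: 16 of 37 were higher and 0 lower, or 21 and 2 adjusted over the list alone. PIWIL4 rose from 92.6 ± 11 to 210 ± 20 CPM (n = 3), the melanoma antigens MAGEB2 from 0.691 ± 0.48 to 12.2 ± 1.3 CPM and MAGEA4 from 53.4 ± 17 to 376 ± 74 CPM, and TDRD9 from 0.238 ± 0.3 to 10.8 ± 2.1 CPM. MHC class I genes had 8 higher and 0 lower of 18, or 10 and 0 adjusted over the list alone. HLA-B was at 1.05 ± 0.12, NLRC5 at 0.98 ± 0.10 and B2M at 0.75 ± 0.10 on the log2 scale. Of 16 class II genes, 2 were higher and 0 lower, or 3 and 0 adjusted over the list alone. The higher class II genes numbered 0, 1 and 1 without gRNF4 DMSO libraries 1, 2 and 3 in turn, 1, 0 and 3 without treated gRNF4 libraries 1, 2 and 3, and 0 without both DMSO libraries numbered 1. CIITA was at 41.5 ± 4.9 CPM with DMSO and 39.5 ± 3.2 CPM with the compound. MPO rose from 25.1 ± 2.5 to 203 ± 15 CPM, ELANE by 1.04 ± 0.16, MNDA by 2.17 ± 0.24 and CD36 by 1.90 ± 0.25.

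Over all genes in gRNF4, edgeR called 659 higher and 212 lower, of which 344 and 68 changed by more than 1 on the log2 scale. Among genes with no read in gRNF4 with DMSO, the dynein gene DNAH8 was at least 18.3-fold higher, MAEL at least 17.6-fold and SLC22A31 at least 13.8-fold. In all, 32 called genes had 0 counts in gRNF4 with DMSO and 0 called genes had 0 counts with the compound. PNMA5 rose from 0.386 ± 0.17 to 22.4 ± 6.4 CPM and ZNF595 from 6.62 ± 4.1 to 53.3 ± 5.8 CPM. NFE2 rose by 1.09 ± 0.15, ADCY9 by 0.69 ± 0.09, HOXA11 by 0.85 ± 0.13, CD4 by 0.67 ± 0.10, SNHG14 by 0.91 ± 0.14, ZBTB4 by 0.72 ± 0.10, DRAM1 by 1.11 ± 0.20 and BCL2L11 by 0.66 ± 0.10. NF-kB targets and cytokines had 7 lower and 0 higher of 28, or 15 and 2 adjusted over the list alone. TNFAIP3 was at -1.23 ± 0.21 and IL1RN at -1.05 ± 0.22. The lower NF-kB genes numbered 2, 4 and 3 without treated gRNF4 libraries 1, 2 and 3 in turn. BCL11A fell by 0.88 (SE 0.15) and PBX3 by 0.52 (SE 0.08). Few cell cycle genes passed. Of 50 S-phase genes 2, and of 56 G2/M genes 0, were lower, and 0 were higher in either list, with the same numbers adjusted over the list alone. Of 60 histone genes 2 were lower and 4 higher, the same adjusted over the list alone. Without both DMSO libraries numbered 1, 8 S-phase and 2 G2/M genes were lower and 0 higher, and 4 histone genes were lower and 6 higher. Of 42 stress-response genes 0 passed in either direction, over all genes or adjusted over the list alone, with a median of -0.37. Interferon-stimulated genes had 6 higher and 0 lower of 76, or 8 and 3 adjusted over the list alone, with a median of -0.06 that was 0.24 without gRNF4 DMSO library 1. The higher ones numbered 1 without gRNF4 DMSO library 3 and at most 4 without any other library of the comparison.

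In gRNF4, 12 lists passed camera, led by the germline list (adjusted p = 2.93e-14, and p = 0.0778 with an estimated correlation), MHC class I (3.93e-10, and p = 0.225 with an estimated correlation) and NF-kB (2.65e-07, and p = 0.507 with an estimated correlation). Others that passed camera were G2/M (adjusted p = 0.00013, and p = 0.713 with an estimated correlation), S phase (0.000402, and p = 0.763) and histones (0.00863, and p = 0.833), all lower. Lower sets also included repair genes (adjusted p = 0.0102, and p = 0.721 with an estimated correlation), the stem and KMT2A list (0.0194, and p = 0.474) and the stress response (0.0231, and p = 0.64). ZNF genes (camera adjusted p = 0.00609, and p = 0.474 with an estimated correlation), granulocyte genes (0.00863, and p = 0.352) and p53 targets (0.0257, and p = 0.507) ranked higher. Histones had camera adjusted p of 0.0681 and 0.0659 without DMSO libraries 2 and 3, and turned direction without treated library 1 (0.987). The stress response stood at -0.04 (camera adjusted p = 0.237) without DMSO library 1 and -0.24 (0.305) without treated library 1. S phase had a camera adjusted p of 0.0989 without DMSO library 3. Repair had 0.215 without DMSO library 3, 0.0554 without treated library 1 and 0.0725 without treated library 2. The stem and KMT2A list had 0.137 and 0.0616 without DMSO libraries 1 and 2, and 0.0716 and 0.0606 without treated libraries 1 and 3. For p53 targets it was 0.0697 and 0.0768 without DMSO libraries 1 and 2, and 0.102 without treated library 3. The number of genes called by edgeR in gRNF4 was 553 without DMSO library 2, 486 without DMSO library 3, 575 without treated library 1 and 469 without treated library 2, against 871 with all libraries. Of the 659 genes higher in gRNF4, 590 were also higher in gNT, against 92.1 for independent lists, and 4 were lower in gNT. Of the 212 lower genes, 142 were shared against 25.8 for independent lists, and 0 were higher in gNT. The comparisons share no library, but same-numbered libraries of the guides deviated together, so they are not independent and part of the overlap and correlation can come from the pairs. Across all 15937 genes the log2 fold changes in gNT and gRNF4 had a Pearson correlation of 0.79 and a Spearman correlation of 0.48, taken over genes, which are not independent replicates.

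The third comparison asked what the RNF4 guide changed in vehicle-treated cells. SCCPDH, a saccharopine dehydrogenase-like gene on chromosome 1 (246724047 to 246768137), was the 1 gene called: it stood at 6.37 ± 0.84 CPM in gNT and 1.83 ± 0.47 CPM in gRNF4 (n = 3), a log2 fold change of -1.78 with SE 0.25 and an edgeR adjusted p of 0.0483. PIWIL4 (101 ± 13 and 92.6 ± 11 CPM), B2M (397 ± 27 and 383 ± 18 CPM) and MPO (24.6 ± 0.8 and 25.1 ± 2.5 CPM) differed by less than 1 SD between the guides. No member of any of the 25 lists passed over all genes, and adjusted over the list alone 1 germline, 1 repair and 1 histone gene were lower. At an unadjusted p under 0.05 edgeR gave 291 genes, while DESeq2 called 4 genes and limma-voom 0 after adjustment. With the replicate number as a block, 3 genes passed. SCCPDH lost its call without any one of the 6 libraries, with edgeR adjusted p from 0.0939 to 0.414. Histones (median -0.10, camera adjusted p = 2.65e-07), stress-response genes (-0.12, adjusted p = 0.00699) and MHC class I genes (-0.06, adjusted p = 0.0431) ranked lower as sets, with adjusted p of 0.568 for each of these 3 sets with an estimated correlation. The stress-response genes stood at 0.02 (camera adjusted p = 0.751) without gNT DMSO library 1 and at 0 (adjusted p = 0.858) without gRNF4 DMSO library 3. Class I genes stood at -0.03 (camera adjusted p = 0.4) and -0.01 (adjusted p = 0.518) in these fits, and at -0.09 (adjusted p = 0.0691) without gNT DMSO library 2. Histones kept their camera call without any one library, with medians from -0.20 to -0.04. Adjusted over the 25 lists of this comparison, the real grouping called 2 lists and other splits of these libraries up to 7. Of the 10 splits, 8 called at least as many as the real one, itself included. The block added the interferon-stimulated genes (median -0.11, camera adjusted p from 0.0745 to 0.0191) and the MHC class II genes (0.14, from 0.0799 to 0.0201). Without the block, their camera adjusted p with an estimated correlation was 0.868 and 0.721.

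The fourth comparison set gRNF4 against gNT among cells given the compound. Germline genes were lower with the RNF4 guide: of 37, 25 were lower and 0 higher, or 26 and 1 adjusted over the list alone. The choice of these 37 by the count filter, described above, can raise this share too. PIWIL4 stood at 439 ± 25 CPM in gNT and 210 ± 20 CPM in gRNF4 (n = 3), PIWIL2 at 24.3 ± 3.5 and 5.82 ± 0.94 CPM, TDRD12 at 12.2 ± 2.7 and 2.6 ± 0.35 CPM, and the cohesin subunit of meiosis STAG3 at 17.7 ± 2.9 and 7.37 ± 0.46 CPM. MHC class I had 6 lower and 0 higher of 18, or 8 and 0 adjusted over the list alone, with NLRC5 at -0.63 ± 0.10 on the log2 scale. Class II had 3 lower and 0 higher of 16, or 8 and 0 adjusted over the list alone. CIITA stood at 78.9 ± 4.3 CPM in gNT and 39.5 ± 3.2 CPM in gRNF4. Interferon-stimulated genes had 6 lower and 0 higher of 76, or 8 and 0 adjusted over the list alone, with IFI27 at 7.73 ± 1 and 1.05 ± 0.55 CPM. The lower interferon-stimulated genes numbered 2, 1 and 6 without treated gNT libraries 1, 2 and 3 in turn, and 5, 3 and 1 without treated gRNF4 libraries 1, 2 and 3. Lower class I genes numbered 1, 1 and 6, then 3, 4 and 1 in the same order, and lower class II genes 1, 1 and 4, then 2, 6 and 1. Without both DMSO libraries numbered 1, which are not compared here, 24 interferon-stimulated genes were lower and 1 higher. In that fit, chosen after seeing the data, 8 class I and 6 class II genes were lower and 0 higher. Retroelement genes had 2 lower and 0 higher of 10, or 5 and 0 adjusted over the list alone, with PNMA5 at -2.18 ± 0.16, and imprinted genes had 4 lower and 0 higher of 34, or 5 and 1 adjusted over the list alone. MPO was lower by the same comparison, at 559 ± 40 CPM in gNT and 203 ± 15 CPM in gRNF4.

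Histone, G2/M and stem-cell genes were among those higher with the RNF4 guide in treated cells, in numbers that depended on single libraries. Histone genes had 29 higher and 3 lower of 60, or 45 and 4 adjusted over the list alone. H3C8 was at 0.72 ± 0.13, with H1-1 (-1.88 ± 0.29) and H3C6 (-0.95 ± 0.16) lower. G2/M genes had 10 higher and 0 lower of 56, or 20 and 0 adjusted over the list alone. The higher G2/M genes numbered 1, 1 and 19 without treated gNT libraries 1, 2 and 3 in turn, and 12, 5 and 1 without treated gRNF4 libraries 1, 2 and 3. SMC4 was at 311 ± 37 CPM in gNT and 484 ± 53 CPM in gRNF4. The stem and KMT2A list had 8 higher and 2 lower of 27, or 11 and 3 adjusted over the list alone. MYC (0.82 ± 0.13), CDK6 (0.73 ± 0.09) and HOXA10 (0.63 ± 0.11) were higher and HOXA13 (-1.50 ± 0.22) lower. The higher members of this list numbered 4 without treated gNT library 1, treated gNT library 2 or treated gRNF4 library 3. Stress-response genes had 5 higher and 0 lower of 42, or 7 and 2 adjusted over the list alone, with SLC7A1 at 0.84 ± 0.15, and 1 was higher without treated gNT library 1. Few repair and S-phase genes passed singly with all libraries in the fit and without the block. Repair genes had 2 higher and 0 lower of 52, the same adjusted over the list alone, with MRE11 at 84.4 ± 11 and 153 ± 7.3 CPM. S phase had 1 higher and 0 lower of 50, the same adjusted over the list alone. Without both DMSO libraries numbered 1, 23 S-phase genes were higher and 0 lower, and 12 repair genes higher and 1 lower. In that fit, chosen after seeing the data, 22 G2/M genes were higher and 0 lower, and 43 histone genes higher and 5 lower. Those DMSO libraries are not compared here and act only through parts of the fit shared by all groups. RNA-editing genes had 3 higher and 0 lower of 20, or 5 and 0 adjusted over the list alone, with ADARB1 at 0.76 ± 0.14 and APOBEC3C at 0.67 ± 0.09. The myeloid genes AIF1 (1.28 ± 0.15), CXCR2 (1.56 ± 0.18) and CTSG (1.88 ± 0.29) were higher. Among the largest differences, CSPG4, a surface proteoglycan, stood at 45.1 ± 9.6 CPM in gNT and 199 ± 52 CPM in gRNF4 and the tight-junction gene CGNL1 at 0.418 ± 0.36 and 3.41 ± 0.78 CPM, while ANO7 (-2.27 ± 0.26) and SUSD3 (-2.34 ± 0.36) were lower in gRNF4. The mitochondrial share was 2.15% ± 0.093 in treated gNT and 1.51% ± 0.29 in treated gRNF4 (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows).

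Over all genes edgeR called 478 higher and 691 lower in treated gRNF4 against treated gNT, and 1519 higher and 1503 lower with the replicate number as a block. Upper-quartile scaling gave 395 higher and 853 lower, and library sizes alone 366 and 838. The camera test passed 14 lists, with adjusted p of 1.44e-16 for the lower germline list (p = 0.0754 with an estimated correlation), 4.09e-05 for class II (p = 0.507), 0.00151 for interferon (p = 0.721), 0.00216 for class I (p = 0.507), 0.00216 for retroelements (p = 0.352) and 0.0156 for imprinted genes (p = 0.538). The higher sets had adjusted p of 3.57e-16 for histones, 3.06e-13 for G2/M, 1.92e-08 for S phase, 7.96e-05 for repair, 0.00624 for RNA editing, 0.00824 for the stress response, 0.0169 for the stem and KMT2A list and 0.0331 for the SUMO pathway. For those higher sets the adjusted p with an estimated correlation was 0.507, 0.538, 0.595, 0.568, 0.352, 0.568, 0.474 and 0.568 in the same order. Without treated gRNF4 library 3, the camera adjusted p was 0.154 for the SUMO pathway and 0.0606 for imprinted genes. Without treated gRNF4 library 3 or treated gNT library 1, edgeR called 293 and 298 genes, with 1 higher histone gene each, and 16 and 14 lower germline genes. Without treated gNT library 2 or treated gRNF4 library 2 it called 555 and 617, with 4 and 7 higher histone genes.

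The fifth comparison tested whether the response to the compound differed between guides. It was smaller with the RNF4 guide for most responsive genes: of 4189 genes changed by the compound on average over both guides, 83.6% had the smaller log2 fold change in gRNF4, with a median change in the direction of the response of 0.678 in gNT and 0.364 in gRNF4. The share was 82.4% for the 2313 genes that rose and 85.1% for the 1876 that fell, and an orthogonal line through 0 had a slope of 0.653. CIITA had an interaction of -1.05 ± 0.16 on the log2 scale (edgeR adjusted p = 0.0144). MPO rose by 4.50 ± 0.11 in gNT and 3.01 ± 0.10 in gRNF4, an interaction of -1.49 ± 0.14 (edgeR adjusted p = 0.000399). AIF1, a calcium-binding protein of macrophages, had a positive interaction of 1.34 ± 0.21 (edgeR adjusted p = 0.0144).

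Over all genes edgeR called 95 interactions, 45 positive and 50 negative, against 2368 at an unadjusted p under 0.05, and 859 with the replicate number as a block. Library sizes alone as the scaling gave 38 positive and 67 negative. Histone genes had 2 positive and 0 negative interactions of 60 over all genes, and 44 and 2 adjusted over the list alone (camera adjusted p = 5.6e-21, and p = 0.474 with an estimated correlation). Germline genes had 2 negative and 0 positive of 37, or 6 and 0 adjusted over the list alone (camera adjusted p = 2.04e-08, and p = 0.225 with an estimated correlation), and class II genes 1 negative and 0 positive of 16, or 6 and 0 adjusted over the list alone (2.43e-05, and p = 0.507 with an estimated correlation). Camera also gave adjusted p of 4.05e-10 for G2/M, 1.21e-07 for S phase, 5.92e-05 for repair, 0.000613 for the stress response, 0.0197 for RNA editing, 0.031 for the SUMO pathway and 0.0328 for the stem and KMT2A list, all positive. With an estimated correlation those adjusted p were 0.538, 0.617, 0.568, 0.538, 0.474, 0.568 and 0.507 in the same order. Without the block, few single members passed: 0 of 56 G2/M, 0 of 50 S-phase and 1 of 52 repair genes. Members were not recounted with the block, which gave more calls over all genes. Adjusted over the list alone they numbered 1, 0 and 1. Retroelement genes (camera adjusted p = 0.0134, and p = 0.474 with an estimated correlation), interferon-stimulated genes (0.0432, and p = 0.863), class I genes (0.0432, and p = 0.568) and imprinted genes (0.0432, and p = 0.568) ranked negative. Several of these camera calls were lost without 1 library. Interferon-stimulated genes had camera adjusted p of 0.28 and 0.258 without gNT DMSO libraries 2 and 3, 0.0922 and 0.277 without treated gNT libraries 1 and 2, 0.684 without gRNF4 DMSO library 1 (median 0.04), and 0.236 and 0.0939 without treated gRNF4 libraries 1 and 3. For class I it was 0.0701 and 0.0859 without gNT DMSO libraries 2 and 3, 0.0517 and 0.191 without treated gNT libraries 1 and 2, 0.094 and 0.119 without gRNF4 DMSO libraries 1 and 2, and 0.254 without treated gRNF4 library 1. For imprinted genes it was 0.0761 without gNT DMSO library 3, 0.0802 without treated gNT library 1, 0.243 without gRNF4 DMSO library 1 and 0.118 without treated gRNF4 library 3. For retroelements it was 0.0584 without gRNF4 DMSO library 2 and 0.0534 without treated gRNF4 library 3. The SUMO pathway had 0.0743 without gRNF4 DMSO library 1 and 0.121 without treated gRNF4 library 3, the stem and KMT2A list 0.0585 without gRNF4 DMSO library 3, and RNA editing 0.0553 without gNT DMSO library 3. Of 27 named interactions, 5 kept their call without any one library: MPO, CIITA, AIF1, the phosphatase PTPRN2 (2.06 ± 0.28) and the collagen gene COL27A1 (1.90 ± 0.28). The number of interactions called ranged from 12 without gRNF4 DMSO library 3, through 17 without treated gNT library 1, 28 without treated gRNF4 library 3 and 29 without treated gNT library 2, to 157 without treated gRNF4 library 1 and 187 without gNT DMSO library 1.

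**Figure D3:**
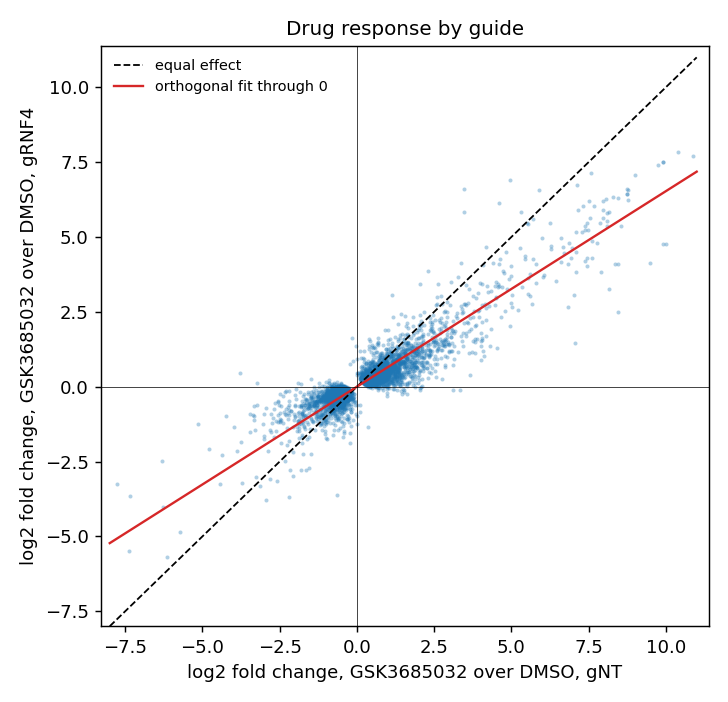
Log2 fold change of GSK3685032 over DMSO in gNT (x axis) against that in gRNF4 (y axis) for the 4189 genes changed on average over both guides; each point is a gene, the dashed line marks equal effects and the solid line is an orthogonal fit through 0 with a slope of 0.653. Of these genes 83.6% had the smaller change in gRNF4.

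Counts outside annotated genes formed a second table of 23361 numbered intergenic features, of which 5123 were tested. In gNT the compound raised 724 and lowered 148 of them, and in gRNF4 it raised 165 and lowered 28 (edgeR). Feature 2719 went from 0 counts to 34.8 ± 9.79 CPM (n = 3, scaled by gene counts) in gNT and feature 16646 from 0 to 20.9 ± 7.78, whereas feature 1102 went from 5.36 ± 2.11 and feature 959 from 3.77 ± 2.47 to 0. Among treated cells 269 features were lower and 33 higher in gRNF4 than in gNT, and with the block 711 passed. Between the guides with DMSO, 0 features passed under edgeR and 0 under DESeq2, with 150 at an unadjusted p under 0.05 in edgeR. The interaction had 21 negative and 4 positive features, and 229 passed with the block. Scaled by the intergenic table itself in place of the gene table, 528 features were higher and 388 lower with the compound in gNT, 97 higher and 175 lower in treated gRNF4 against treated gNT, and 20 interactions were positive and 18 negative. Without treated gNT library 1, treated gRNF4 library 3 or treated gRNF4 library 2, the difference between guides in treated cells numbered 102, 121 and 150 features.

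Intergenic features took 4.36% ± 0.63 of all counts in gNT with DMSO (n = 3) and 6.2% ± 0.74 with the compound, a difference of 1.83 percentage points (exact permutation test, two-sided, p = 0.1, the smallest possible for 3 against 3). In gRNF4 the share was 4.69% ± 0.68 with DMSO and 4.56% ± 0.81 with the compound (difference -0.133, exact p = 0.9). Averaged over both guides the compound raised the share by 0.85 points (exact p = 0.13 over 400 arrangements within guides). The difference between the guides in that change was -1.97 points (exact p = 0.05 over 400 arrangements of guide labels within treatment). That test did not use the same-numbered pairs. Within pairs 1, 2 and 3, gRNF4 lay 1.5, 1.35 and 2.07 points below gNT with the compound and 0.31, 0.02 and 0.65 points above it with DMSO. With guide labels exchanged only within pairs, a test chosen after seeing the data, the exact two-sided p was 0.0312, the smallest that 64 arrangements allow. That p needs the sign of every pair difference, among them the 0.02 points of pair 2 with DMSO. Single libraries ranged from 3.961% (95% exact binomial interval 3.947 to 3.975) in gNT DMSO library 3 to 6.981% (6.96 to 7.003) in treated gNT library 1, and in each group library 1 had the highest share.

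**Figure D4:**
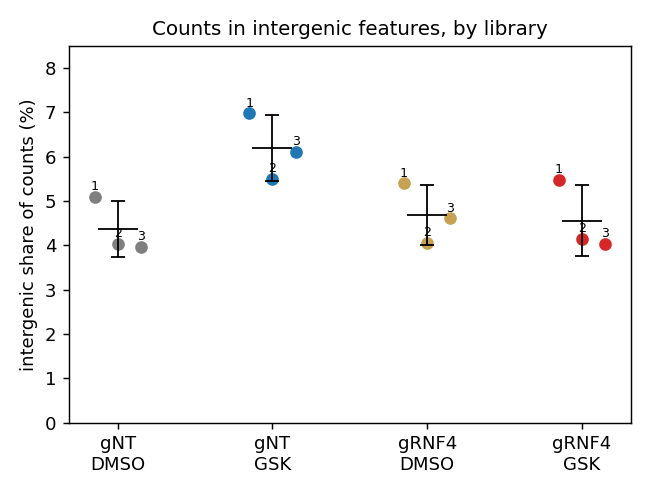
Percent of all counts in intergenic features (y axis, from 0) in each library; points are single libraries with their replicate number, the long bar is the mean of 3 and the whiskers are 1 SD. The gNT libraries with the compound lay between 5.501% and 6.981%, and all other libraries between 3.961% and 5.485%.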

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

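The tests of scaling, of dilution and of added background below were chosen after the result was seen, as was the setting without both DMSO libraries numbered 1. The items here are those where the response to the compound differed between the guides by the interaction test of edgeR or camera: 95 genes and 25 intergenic features, and 14 gene lists.

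On the log2 scale the interaction was 2.10 for CSPG4, 2.06 for PTPRN2, 2.02 for CTSG, 1.96 for GPT2, 1.90 for COL27A1 and 1.78 for SCCPDH. SCCPDH was already lower with the RNF4 guide in DMSO, by as much as this interaction. That DMSO call was lost with any 1 of its libraries left out. It was -3.95 for KIF17, -3.24 for IFI27, -2.93 for C12orf40, -2.49 for XACT, -2.42 for DCAF4L1 and -2.42 for CSMD1. Among list members it was -0.94 for PIWIL4, -1.33 for STAG3, -1.42 for IFITM3, -1.05 for CIITA and -1.49 for MPO, and 0.74 for MRE11, 1.34 for AIF1, 1.19 for CXCR2, 0.97 for MYC, 0.66 for CDK6, 1.01 for SLC7A1, 0.91 for ZNF579, 1.74 for ZNF555, 1.11 for H3C8 and 0.99 for H3C3. KIF17 had 1 to 3 counts in gNT with DMSO, so its fitted value depends on the prior count; its levels were 0.0971 and 15.5 CPM in gNT and 0.73 and 6.27 CPM in gRNF4, with DMSO and the compound. Intergenic features 19408 (4.40) and 14135 (2.32) had positive interactions, and 8191 (-4.77) and 3298 (-7.26) negative ones, the last fitted against a group at 0. MPO, PTPRN2, COL27A1, CIITA and AIF1 kept their call with any 1 library left out.

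Camera gave adjusted p of 2.04e-08 for germline, 2.43e-05 for MHC class II, 0.0134 for retroelement, 0.0432 for interferon-stimulated, 0.0432 for MHC class I and 0.0432 for imprinted genes, all toward a weaker rise or lower level with the RNF4 guide. It gave 5.6e-21 for histones, 4.05e-10 for G2/M, 1.21e-07 for S phase, 5.92e-05 for repair, 0.000613 for the stress response, 0.0197 for RNA editing, 0.031 for the SUMO pathway and 0.0328 for the stem and KMT2A list, all positive. With an estimated correlation 0 of these lists passed, the smallest adjusted p being 0.225 for germline genes.

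The first pattern is the smaller response to the compound in gRNF4, seen in 83.6% of 4189 genes. A difference in scaling would shift all genes by 1 constant, yet with library sizes alone the share stayed at 82.9% (jackknife SE 8.04) for genes that fell and 87% (SE 3.3) for those that rose, which argues against it. Dilution by cells or RNA without a response would leave 1 common fraction for all genes, yet the median linear fraction was 0.612 (SE 0.081) for genes lowered below -0.5 and 0.304 (SE 0.063) for genes raised above 2. Both sets were chosen by fold change in the same libraries and held fixed in the jackknife, so the SE leaves that choice out. With that limit, the difference of 0.308 (SE 0.107) argues against 1 fraction common to these sets, which were the highest and lowest of 5. The others were 0.391 (SE 0.1) for less lowered genes, 0.556 (SE 0.068) for genes raised up to 1 and 0.447 (SE 0.081) for those raised by 1 to 2, and fractions that vary between genes were not tested. Other splits of the libraries came as far from 50% in 7 of 100 cases, the real one included (33.6, highest other 35.7). Chance is not excluded by that count, which can hardly decide it, since 15 of the 100 splits kept the treated libraries parted by guide. All 7 were among these 15, and the highest of the 85 others was 30.7. A smaller effect of the compound with reduced RNF4, which the design names, may underlie the pattern and stays untested against differences in exposure or growth between the cultures. The sample descriptions give the same RNF4 guide name in all gRNF4 libraries. Effects of that guide other than on RNF4 therefore cannot be told apart from reduced RNF4.

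The second pattern is the higher intergenic count with the compound in gNT. The same amount of background added to each of the 5123 tested features would raise those below the mean count more than the sum of these features. In gNT with DMSO the median feature had 21.3 counts and the mean was 57.4. The median log2 fold change (0.3) lay below the log2 ratio of the sums (0.47), a difference of -0.17 (SE 0.0394). That argues against an equal addition as the whole rise. The sums include the 724 features called higher, so an equal addition as part of the rise is not excluded. Scaled by the intergenic table itself, the median was -0.04. Background that differs between features was not tested. Transcripts started outside genes, or read through from genes, could each give such counts and were not told apart, since the features have no positions in the sources used here.

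The numbers of calls were also set against other splits of the libraries. Each comparison of a pair of groups has 10 splits, too few for a share under 0.05. Splits with as many genes as the real one, itself included, numbered 1 for the compound in gNT (real 4168, highest other 0), 1 in gRNF4 (871 and 1), 2 for the guide with DMSO (1 and 6) and 1 for the guide with the compound (1169 and 1). Among intergenic features they numbered 1 (872 and 0), 1 (193 and 1), 10 (0 and 28) and 1 (302 and 0) in the same order. List counts, adjusted over the 25 lists of a comparison and not over 125 tests, were matched in 1 (15 and 12), 2 (12 and 12), 8 (2 and 7) and 1 (14 and 13) splits. For the interaction 8 of 100 splits gave as many genes (95, highest other 2165). As many intergenic features came in 13 (25, highest other 426) and as many lists in 7 (14, highest other 16), so chance is not excluded by these counts. They can hardly decide it: 15 of the 100 splits kept the treated libraries parted by guide, and so kept the treated guide difference. The 8 and 13 were all among these 15, and the other 85 gave at most 0 genes and 1 intergenic feature. The 7 splits with a larger gene count placed both DMSO libraries numbered 1 on the same side, which points to a structure of the samples. Among guide splits that part 3 same-numbered pairs, the 3 others gave at most 0 genes with either treatment, and the 6 that part 1 pair gave at most 6 with DMSO and 1 with the compound.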

How the results depend on the processing

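The fit without both DMSO libraries numbered 1 and the permutation of the intergenic share within pairs were chosen after seeing the data; the other alternatives were set before. Over all settings, named genes kept direction and call in 4325 cases, lost the call in 533 and reversed in 2, lists did so in 484, 112 and 1, and counts or shares stayed within bounds in 220 and moved in 116. DNMT1 between guides with DMSO, not called, turned to 0.04 without gNT DMSO library 3 and 0.05 without gRNF4 DMSO library 1 (range -0.13 to 0.05), and the histone list with the compound in gRNF4 turned direction in camera without treated gRNF4 library 1 (median -0.04, range -0.35 to -0.04). An added threshold of 1 on the log2 scale left 1375 genes for the compound in gNT, 412 in gRNF4, 396 for the guide with the compound and 61 interactions, by construction. For the guide with DMSO the count was 0 with upper-quartile factors, 0 with library size only, 4 with DESeq2, 0 with limma-voom, 8 with no low-count filter, 3 with the replicate block, 2 without both DMSO libraries numbered 1 and 0 with only the groups compared (291 at an unadjusted p under 0.05 in edgeR). For the guide with the compound it was 2192 with no filter, 3022 with the replicate block, 2894 without both DMSO libraries numbered 1 and 2353 with only the groups compared. Interactions numbered 262 with DESeq2, 587 with no filter, 859 with the replicate block and 295 without both DMSO libraries numbered 1. Intergenic features numbered 360 for the compound in gRNF4 and 711 for the guide with the compound under the block, and 492 for the latter without both DMSO libraries numbered 1. Intergenic interactions numbered 38 with factors of the intergenic table, 82 with no filter, 78 with DESeq2 and 229 with the block. The interaction of the intergenic share (-1.97) passed 0.05 with the replicate block, as labels exchanged within pairs (exact p = 0.0312), and not without it (p = 0.05). The pass within pairs hangs on the sign of a difference of 0.02 points in pair 2 with DMSO. Of the list tests, 0 passed with an estimated correlation, and among genes called in either guide 92.1% had the smaller effect in gRNF4. For the guide with the compound, DMSO libraries are not compared, so leaving them out acts only through parts of the fit shared by all groups. Genes called in either guide were mostly called in gNT (4168 against 871 in gRNF4), a choice that favours a larger effect there. The cause was not tested for the other changes.

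With single libraries left out, genes called ranged from 2538 to 4541 for the compound in gNT, 469 to 679 in gRNF4, 0 to 1 for the guide with DMSO, 293 to 1307 for the guide with the compound and 12 to 187 for the interaction; intergenic features from 102 to 366 for the guide with the compound and 7 to 73 for the interaction. The lowest came without treated gNT library 1, treated gRNF4 library 2, any of 5 DMSO libraries, treated gRNF4 library 3, gRNF4 DMSO library 3 and, for both intergenic counts, treated gNT library 1; fewer samples are part of each change and other causes were not tested. For the comparisons of treatments the replicate numbers were not read as pairing (correlations 0.17, 0.03 and 0.16 in gNT and 0.09, 0.07 and 0.23 in gRNF4), though 10 of 12 libraries correlated best with their own number; the replicate block gave 5414 genes in gNT and 1590 in gRNF4. Beyond the values given beside the comparisons between guides, the block changed no other call of a list there.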

Other observations

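The test of the stress-response list in gRNF4 below was chosen after the result was seen, as was the setting without both DMSO libraries numbered 1. The SE of the medians without those libraries was also chosen then, and the rule in gRNF4 was made stricter: a state of those libraries needs a median within 0.1 of 0 that moved by more than 2 SE. With the adjusted p alone, the gRNF4 values would have been read as such a state.

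The pattern is the lower level of stress-response and amino acid genes with the compound. The DMSO libraries numbered 1 stood apart from the others, so a state of those libraries could give it. Without both, the median in gNT was -0.47 (against -0.64 with all libraries), the camera adjusted p was 0.000377, and 16 genes were lower and 4 higher of 42. With an estimated correlation, run with all libraries only, the camera adjusted p in gNT was 0.538. The jackknife SE was 0.0463 over the libraries left, with medians from -0.47 to -0.32 when 1 more library was left out. This argues against a state of those libraries as the whole cause in gNT, though with the SE over all libraries (0.288) the median lay within 2 SE of 0. In gRNF4 the median without both was -0.04 (SE 0.2 over the libraries left and 0.309 over all, against -0.37) and the camera adjusted p 0.223. That spread is too wide, so in gRNF4 an effect of the compound and a state of those libraries cannot be told apart. An effect of the compound, which the design names, stays untested against differences in growth between the cultures.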
